A study of Arabidopsis thaliana with 12 samples.

How the data were processed

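Expression was measured by bulk RNA-seq of total RNA from dissected siliques of Arabidopsis thaliana, in seeds and in the fruit left after the seeds were taken out, for Col-0 and lhp1-6. Per the labels' protocols, each replicate was a pool of 3 to 5 siliques, RNA was extracted with a column kit, and libraries were read on a DNBSEQ instrument as 100 bp paired ends. The labels do not say whether the pools came from separate plants, so p-values measure the spread between these samples, which may be partly technical. Among genes above 0 in both of any 2 libraries, the largest share with exactly equal TPM was 0. Groups and replicate numbers were taken from the labels.

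Per the submitters' processing notes, the processing used cutadapt 1.9.1, STAR 2.5 and featureCounts (version not given in the sources used here) with TAIR10. The library strandedness and the genes' lengths were not given in the sources used here, so reads of overlapping, antisense or near-identical genes were not separated. The values deposited by the authors were TPM per gene, per the labels, 1 table per library with 26925 genes listed. Of the TPM total, 1.33% to 2.23% per library was not among the listed genes, and 1868 genes were at 0 in each library. TPM keep no sequencing depth, so the depth per library is unknown beyond the minimum in the labels, and no counting intervals were made. A TPM is a share of a total, so a large rise of a few abundant genes lowers the values of all others.

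The tests were made with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), a pseudocount of 1, over the 19946 genes with at least 1 TPM in at least 3 libraries. One mean per group was fitted over all 12 libraries, with moderated variances that follow the mean expression, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were lhp1-6 against Col-0 in fruit and in seed, the difference of these effects, and seed against fruit in each genotype. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 35 lists with at least 3 tested members, and again with a correlation estimated per list. No list was called in any of the 5 comparisons with an estimated correlation, when 3 lists in fruit, 6 in seed and 3 in the difference had an unadjusted p under 0.05. Members were also counted past the threshold over all genes and adjusted over the list alone. The lists covered hormone pathways, dormancy and maturation, chromatin, floral and fruit patterning, wall, stress, clock and metabolic genes, organelle-encoded genes and markers of guard cells, vasculature and pollen. The overlap between tissues was set against the product of the counts over the genes tested. Gene names and gene order came from the TAIR10.1 annotation, in which 26715 identifiers matched and 10064 had a symbol, and as the build differs no coordinates are given.

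The design, lists, tests and alternatives were fixed before the data were examined, except where the text says otherwise. The rule for named genes took LHP1, the 10 genes per direction with the largest change among those past the threshold with no overlap between genotypes and a mean of at least 5 TPM in the higher group, and up to 4 members per list by smallest adjusted p. It always took DOG1, MFT, FT, FLC and the tested abscisic acid biosynthesis, catabolism and transport genes, and 5 genes per direction for the difference between tissues and for seed against fruit in Col-0. A part of these genes is given in the text.

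Same-numbered fruit and seed libraries deviated together from their group means, with correlations across genes of 0.192, 0.113 and 0.185 in Col-0 and 0.311, 0.202 and 0.128 in lhp1-6. The numbers were therefore treated as pairing fruit and seed within a genotype, and for comparisons between tissues and the difference of the effects the blocked value is given where it changed the call or moved a count by over 1.5 times. Between genotypes the numbers did not pair the libraries, and no blocked value is given beside those results.

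The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-of-ratios rescaling, quantile normalisation, TPM recomputed without storage and organelle genes, array weights, no mean trend in the variances, variances moderated robustly against outlying genes, the 6 libraries of a comparison alone, a minimum change of 1 log2 unit, the replicate block, and each library left out in turn. Taking an estimated share of seed RNA off the fruit libraries, and the block together with rescaling, were added after seeing the data. The share was the 1st percentile of the fruit over seed TPM ratio among genes at 50 TPM or more in each seed library of the genotype. Genes of the storage and late embryogenesis lists were left out of it. That part of the genotype's mean seed TPM was subtracted, not of the same-numbered seed library. Values below 0 were set to 0, and the rest was scaled up.

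The steps were tested on simulated data for all 19946 genes, in 5 draws of 200 changed genes each. The noise was drawn independently for each gene and library, with the same SD in each group. Library deviations shared by many genes, such as an unequal share of seed RNA, were not simulated, so the rates do not cover them. Nor do they cover an unequal spread between the tissues. Replicates of a group correlated at 0.9532 to 0.988 in fruit and at 0.9893 to 0.9947 in seed (Pearson's r). For fruit, 76.4% of changes of 1 log2 unit and 95.8% of changes of 2 log2 units were recovered, with 4.86% false calls. For seed these values were 78%, 94% and 5.6%, for the difference between tissues 58.2%, 88.2% and 5.06%, for the tissues in Col-0 78.2%, 93.6% and 4.34%, and for the tissues in lhp1-6 75.2%, 92% and 6.28%. For the list test, run on the fruit contrast, the shifted list was found and 0 others among the 35 lists were called in simulated data. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.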

Results

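The series compared siliques of wild-type Arabidopsis thaliana (Col-0) with those of lhp1-6, a mutant of LIKE HETEROCHROMATIN PROTEIN 1, a chromodomain protein of the Polycomb system. Each silique was dissected by hand into seeds and the remaining fruit, giving 4 groups of 3 libraries, 12 bulk RNA-seq libraries in all. The title of the series places the work in the question of how the climate of the mother plant reaches the seed through hormone transport. Plants grew at 22 °C until bolting and then at 16 °C by day and 14 °C by night, and seeds were taken at the bent-cotyledon stage, 14 to 15 days after pollination. The listed TPM values summed to between 977751 and 986706 per library. Genes at 1 TPM or more numbered from 17620 to 19086 per library, and the 10 most abundant genes held from 6.59% to 14.7% of the listed TPM. The first principal component (89.0% of the variance) parted the tissues, with Col-0 fruit replicate 1 nearer to the seeds than any other fruit library, and the second (4.79%) parted the genotypes. Values below are mean TPM ± SD with n = 3 libraries per group, and changes are lhp1-6 minus Col-0 on the log2(TPM + 1) scale, which understates changes of genes near the floor.

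The targeted gene was low in each library labelled lhp1-6. LHP1 (AT5G17690) stood at 15.3, 17.5 and 18.0 TPM in the Col-0 fruit replicates and at 0.817, 0.858 and 0.699 TPM in lhp1-6 fruit. The Col-0 seed replicates held 20.8, 23.7 and 21.3 TPM, against 0.310, 0.370 and 0.382 TPM in lhp1-6 seed. LHP1 thus fell from 16.9 ± 1.40 to 0.791 ± 0.0826 TPM in fruit, a change of -3.32 (SE 0.10, adjusted p = 5.41e-08), and from 21.9 ± 1.57 to 0.354 ± 0.0387 TPM in seed, a change of -4.08 (SE 0.10, adjusted p = 6.06e-09).

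**Figure D1:**
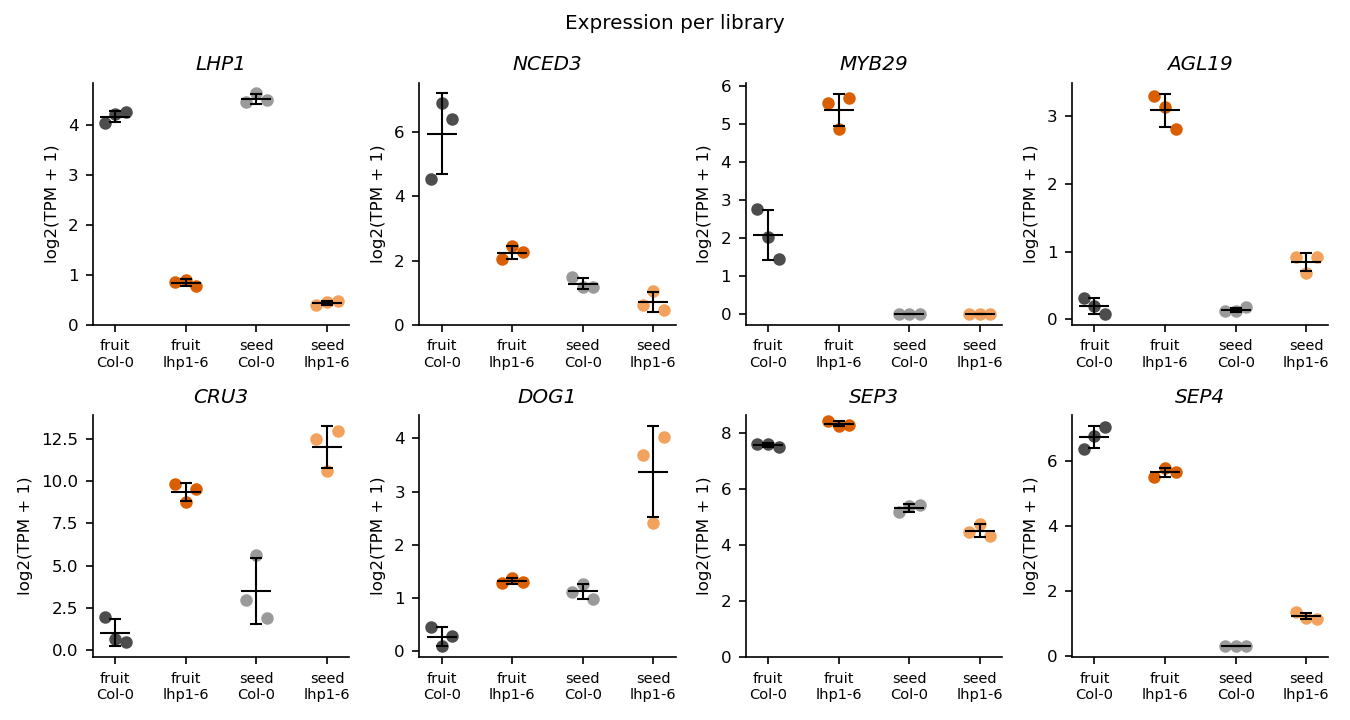
Expression of LHP1, NCED3, MYB29, AGL19, CRU3, DOG1, SEP3 and SEP4 in the 4 groups, on the log2(TPM + 1) scale. Points are libraries and bars are the mean ± SD of 3 libraries. LHP1 lies below 1 TPM in each lhp1-6 library, NCED3 is lower and MYB29 higher in lhp1-6 fruit, and CRU3 and DOG1 are higher in lhp1-6 seed.

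Fruit of lhp1-6 held less of several abscisic acid, defence and senescence transcripts and more of several glucosinolate and storage protein transcripts, the storage calls ending with the estimated seed share taken off the fruit libraries. The largest fall under the naming rule was that of NCED3 (AT3G14440), a dioxygenase at the rate-limiting step of abscisic acid synthesis, from 75.5 ± 49.3 to 3.79 ± 0.659 TPM (-3.71, SE 0.47, adjusted p = 0.000741). Its Col-0 replicates were spread, at 22.1, 119 and 84.9 TPM, and its lhp1-6 replicates lay at 3.14, 4.45 and 3.78 TPM. Of 19946 genes tested, 2980 changed, 1146 higher and 1834 lower (38.5% higher). After median-of-ratios rescaling 1438 were higher and 1672 lower, and after quantile normalisation 1665 were higher and 1504 lower, so the balance of directions depended on the scaling. Changes of at least 1 log2 unit numbered 300 higher and 432 lower.

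Among the other genes with the largest falls were those of the senescence regulators WRKY53 (AT4G23810, -3.29, adjusted p = 0.0107) and NAP (AT1G69490, -3.04, adjusted p = 0.00108). WSD1 (AT5G37300), a wax ester synthase, fell from 38 ± 12.7 to 4.66 ± 0.492 TPM (-2.74, adjusted p = 1.81e-05). The germin-like genes AT5G39150 (-2.93) and AT5G39180 (-2.89) fell as well, but they are near-identical copies whose reads the counting could split. AT3G59845 fell from 203 ± 30.3 to 22.5 ± 10 TPM (-3.19, adjusted p = 2.59e-05). AT5G59330 (-2.81) and AT4G10290 (-2.65) completed the genes with the largest falls under the naming rule. CRK10 (-2.75) fell by more than AT4G10290 and was not named by that rule. The WRKY53 call was lost with the 6 fruit libraries alone (adjusted p = 0.0978). The largest rises were dominated by storage protein genes, described below, and included TGG1 (AT5G26000), a myrosinase, from 29.2 ± 20.8 to 554 ± 253 TPM (4.30, adjusted p = 0.000853).

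Abscisic acid genes moved in several steps of the pathway. Of 8 biosynthesis genes tested, 3 fell and 5 did not pass, and adjusted over the list alone 3 fell. The list test gave adjusted p = 0.633, with a median of 0.09 and a mean of -0.48. Beside NCED3, ABA1 (AT5G67030), the zeaxanthin epoxidase, changed by -0.56 (SE 0.09, adjusted p = 0.0026) and ABA4 (AT1G67080) by -0.34 (adjusted p = 0.0325). The ABA4 call was lost after median-of-ratios rescaling and quantile normalisation (adjusted p = 0.0779 and 0.0878), and without Col-0 replicate 3 or any 1 lhp1-6 replicate (adjusted p up to 0.0807). Of 8 catabolism and conjugation genes 3 fell and 1 rose, and the list test pointed lower (median -0.81, adjusted p = 0.0399, and 0.678 as adjusted p with an estimated correlation). The hydroxylases CYP707A1 (AT4G19230, -1.01, adjusted p = 0.00546) and CYP707A2 (AT2G29090, -1.34, adjusted p = 0.000865) and the glucosyltransferase UGT71B6 (AT3G21780, -1.53, adjusted p = 0.00684) fell, whereas BGLU18 (AT1G52400), a glucosidase that frees abscisic acid from its conjugate, rose (1.54, adjusted p = 0.00463). Adjusted over the list alone, 3 fell and 1 rose. The calls of ABA1, ABA4, CYP707A1, UGT71B6 and BGLU18 were lost with the 6 fruit libraries alone (adjusted p = 0.0599, 0.159, 0.0510, 0.0798 and 0.0515).

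Of 21 abscisic acid signalling and response genes 6 fell, none rose and 15 did not pass, and adjusted over the list alone 12 fell (median -0.56, adjusted p = 0.000128, and 0.678 as adjusted p with an estimated correlation). Examples were AFP1 (AT1G69260), an ABI5-binding protein (-1.74, adjusted p = 0.00515), the transcription factor ABF3 (AT4G34000, -0.86, adjusted p = 0.0036) and the phosphatase HAB1 (AT1G72770, -0.89, adjusted p = 0.00625). ABI5 (AT2G36270) changed by -0.70 (adjusted p = 0.0244), a call lost without lhp1-6 replicate 2 or 3 (adjusted p up to 0.0827). Of 11 transporters of abscisic acid 2 rose and 1 fell, with no list call (adjusted p = 0.633). The exporter DTX50 (AT5G52050) rose from 2.02 ± 0.882 to 5.69 ± 1.26 TPM (1.18, adjusted p = 0.00491). ABCG20 (AT3G53510) was higher (1.10, adjusted p = 0.0408) and ABCG18 (AT3G55110) lower (-0.81, adjusted p = 0.0328). The first call was lost without Col-0 replicate 2 or 3 or lhp1-6 replicate 1 or 2 (adjusted p up to 0.141) and with the seed share taken off the fruit libraries, as given below (adjusted p = 0.621). It was also lost with a pseudocount of 5, no filter or array weights (adjusted p up to 0.130). The second call was lost without Col-0 replicate 2 or lhp1-6 replicate 2 or 3 (adjusted p up to 0.104). With the 6 fruit libraries alone the calls of AFP1, HAB1, ABI5, DTX50, ABCG20 and ABCG18 were lost (adjusted p = 0.0614, 0.0754, 0.136, 0.0640, 0.0913 and 0.154).

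The lists of defence, senescence, gibberellin catabolism and secondary wall genes were called lower in lhp1-6 fruit, but not with an estimated correlation. Of 9 salicylic acid and pathogen defence genes 5 fell, 6 when adjusted over the list alone (median -1.004, adjusted p = 0.000884, and 0.225 as adjusted p with an estimated correlation). They included WRKY70 (AT3G56400, -1.70, adjusted p = 0.00699), PR1 (AT2G14610), a marker of salicylic acid response (-1.63, adjusted p = 0.00581), ICS1 (AT1G74710), the isochorismate synthase of salicylic acid synthesis (-1.004, adjusted p = 0.00104), and PAD4 (AT3G52430, -0.85, adjusted p = 0.00304). Of 15 senescence genes 4 fell, also 4 adjusted over the list alone (median -0.36, adjusted p = 0.0121, and 0.678 as adjusted p with an estimated correlation). Beside NAP and WRKY53 these included NAC092 (AT5G39610, -0.84, adjusted p = 0.0032). Of 4 gibberellin catabolism genes 3 fell (2 after median-of-ratios rescaling; 3 adjusted over the list alone), among them GA2OX1 (AT1G78440, -1.37, adjusted p = 0.000579), and the list gave adjusted p = 0.0196 (0.27 as adjusted p with an estimated correlation). Of 21 secondary wall and lignin genes 6 fell, 8 adjusted over the list alone (adjusted p = 0.0121, and 0.867 as adjusted p with an estimated correlation), among them NST3 (AT1G32770), a switch of secondary wall formation (-0.91, adjusted p = 0.0104). The vascular marker XCP1 (AT4G35350), a xylem protease, rose (0.92, adjusted p = 0.00139), as 1 of 5 vascular markers. The calls of WRKY70, PR1, PAD4 and NST3 were lost with the 6 fruit libraries alone (adjusted p = 0.0758, 0.0754, 0.0593 and 0.0901).

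The glucosinolate list was called higher, but not with an estimated correlation. Of 10 genes tested 4 rose, and adjusted over the list alone 6 rose and 1 fell (median 1.05, adjusted p = 0.000194, and 0.27 as adjusted p with an estimated correlation). MYB29 (AT5G07690), a regulator of aliphatic glucosinolate synthesis, stood at 5.81, 3.04 and 1.72 TPM in Col-0 fruit and at 46.0, 28.6 and 51.0 TPM in lhp1-6 fruit (3.305, adjusted p = 7.97e-05). TGG2 (AT5G25980), like TGG1 a myrosinase of guard cells and phloem, rose from 51.3 ± 56.7 to 479 ± 123 TPM (3.76, adjusted p = 0.00229), and the pair share enough sequence for reads to be split between them. None of the 6 guard cell markers changed in fruit (limma, 1 at an unadjusted p under 0.05, list adjusted p = 0.392).

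Storage protein and oleosin genes showed the largest rises in fruit. Of 13 genes 9 rose, 10 adjusted over the list alone (median 3.94, adjusted p = 4.45e-09, and 0.54 as adjusted p with an estimated correlation). CRU3 (AT4G28520), a cruciferin, stood at 2.88, 0.571 and 0.415 TPM in Col-0 fruit and at 903, 436 and 723 TPM in lhp1-6 fruit (8.33, adjusted p = 0.000243). Rises followed for SESA1 (AT4G27140, 6.42), SESA2 (AT4G27150, 5.74), CRU2 (AT1G03880, 5.63), CRU1 (AT5G44120, 5.47) and SESA5 (AT5G54740, 4.85). The albumin and cruciferin copies resemble each other, so single values are uncertain. AT5G50600 (4.27) and AT5G50700 (4.26), a near-identical pair of hydroxysteroid dehydrogenase genes, and AT1G03103 (3.95) also rose.

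The fruit libraries held transcripts of seed genes to unequal degrees. The share of seed RNA was taken as the 1st percentile of the fruit over seed TPM ratio among genes at 50 TPM or more in seed. Storage and late embryogenesis genes were left out of this estimate. The Col-0 fruit replicates held 23.4%, 3.69% and 5.65%, and the lhp1-6 replicates 8.31%, 11.2% and 9.12%. The storage list had a median fruit over seed ratio of 25.8%, 4.07% and 2.12% in the Col-0 fruit replicates and of 13.0%, 8.38% and 9.65% in lhp1-6. This median covers the members at 50 TPM or more in seed, 10 in Col-0 and 13 in lhp1-6. With the seed share taken off, an alternative chosen after seeing the data, no call was left for CRU3, SESA1, SESA2, CRU2, CRU1, SESA5, AT5G50600, AT5G50700 or AT1G03103 (adjusted p up to 0.246). Their changes lay between 1.77 (SE 0.81, AT5G50700) and 5.75 (SE 1.94, CRU3) with the share off, against 3.95 (SE 0.67, AT1G03103) to 8.33 (SE 0.88, CRU3) before, so the changes shrank and the spread grew. Taking off the genotype's mean seed value, rather than that of the same-numbered library, may add to the spread. The ABCG20 call ended too, as its change went from 1.10 (SE 0.32) to 0.32 (SE 0.42, adjusted p = 0.621). DOG1 (AT5G45830), the dormancy regulator, was at 0.219 ± 0.152 TPM in Col-0 fruit and 1.5 ± 0.0922 TPM in lhp1-6 fruit (adjusted p = 0.053), and passed without Col-0 replicate 1 (adjusted p = 0.0392), with a pseudocount of 0.1 (0.00782) and with the 6 fruit libraries alone (0.0195). It did not pass under the other alternatives, and over all of them its change lay between 0.318 and 2.45, with adjusted p up to 0.358. MFT (AT1G18100), a phosphatidylethanolamine-binding protein gene of seed germination, did not pass (0.89, adjusted p = 0.334). It passed without Col-0 replicate 1 (0.00155) and with array weights (0.0365). Without that replicate the Col-0 shares of seed RNA were 3.69% and 5.65%, each below every lhp1-6 share. The DOG1 and MFT calls gained without it can therefore not be told apart from an unequal share of seed RNA. In the 13 dormancy regulators 1 gene rose, 3 adjusted over the list alone (list adjusted p = 0.974; median -0.12 and mean 0.14). Of 7 late embryogenesis genes 2 rose (adjusted p = 0.0804), of 9 seed oil genes 1 rose and 1 fell (list adjusted p = 0.633), and none of 7 embryo regulators changed (limma, 0 at an unadjusted p under 0.05; 0.856).

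**Figure D2:**
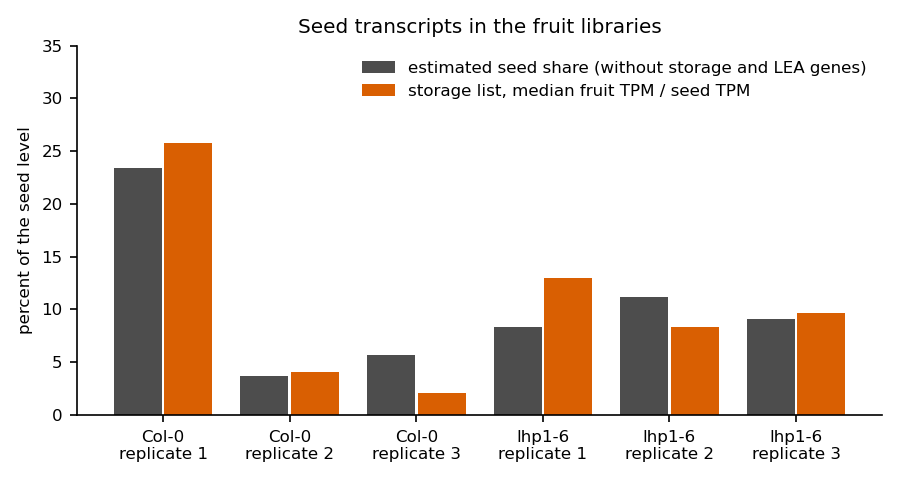
Estimated share of seed RNA and median fruit over seed TPM ratio of the storage protein list, both in percent, for each of the 6 fruit libraries. The ratio covers 10 members of the list in Col-0 and 13 in lhp1-6. Col-0 fruit replicate 1 lies highest, with 23.4% and 25.8%, and the lhp1-6 libraries lie between 8.31% and 13.0%.

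Floral and flowering regulators went both ways in fruit. Of 15 floral and ovule MADS-box genes 3 rose and 4 fell, with a test direction of higher against a median of -0.09, which flipped after quantile normalisation (adjusted p = 0.974). SEP3 (AT1G24260, 0.77, adjusted p = 0.00153), PI (AT5G20240, 1.06, adjusted p = 0.00148) and SHP1 (AT3G58780), a valve margin identity gene (0.60, adjusted p = 0.00329), rose, and SEP4 (AT2G03710) fell (-1.09, adjusted p = 0.00108). Of 16 flowering time genes 2 rose and 3 fell (list adjusted p = 0.856). AGL19 (AT4G22950) rose from 0.149 ± 0.0893 to 7.56 ± 1.42 TPM (2.89, adjusted p = 1.02e-06), and TSF (AT4G20370), a relative of FT, fell (-2.29, adjusted p = 0.000838). FLC (AT5G10140), the floral repressor, was higher (1.10, adjusted p = 0.0461), a call lost without Col-0 replicate 2 or 3 or any 1 lhp1-6 replicate (adjusted p up to 0.152). FT (AT1G65480) did not pass (-0.08, adjusted p = 0.877), and its sign turned to 0.095 without Col-0 replicate 3. The FLC call was also lost with a pseudocount of 0.1, no filter or no mean trend (adjusted p = 0.0531, 0.0556 and 0.0512), and with the 6 fruit libraries alone those of FLC, SHP1, VIN3 and ATX1 were lost (adjusted p = 0.203, 0.0512, 0.0637 and 0.0703). Of 25 Polycomb and related genes, LHP1 included, 2 rose and 4 fell (adjusted p = 0.457), with VIN3 (AT5G57380), which acts in vernalisation, higher (0.77, adjusted p = 0.00687) and ATX1 (AT2G31650), a trithorax-type methyltransferase, lower (-1.14, adjusted p = 0.00567). Of 13 valve margin genes 3 rose and 1 fell (list adjusted p = 0.0804), and ADPG1 (AT3G57510), a dehiscence polygalacturonase, rose (1.80, adjusted p = 0.000207). Of 8 meristem genes STM (AT1G62360) alone changed (-1.63, adjusted p = 0.000396; list adjusted p = 0.308).

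Of 11 clock genes 4 fell and 3 rose in fruit, with no list call. The falls included CCA1 (AT2G46830, -1.24, adjusted p = 0.000721), LHY (AT1G01060, -1.55, adjusted p = 0.0013) and RVE8 (AT3G09600, -1.10, adjusted p = 0.00644), which peak in the morning. The 3 that rose were LUX (AT3G46640, 0.83, adjusted p = 0.000126), TOC1 (AT5G61380, 0.59, adjusted p = 0.0414) and ELF4 (AT2G40080, 0.69, adjusted p = 0.0377), which peak towards the evening. Others of these phases did not pass, namely PRR9 (AT2G46790, -0.66, adjusted p = 0.0985), of the morning, and PRR5 (AT5G24470, 0.999, adjusted p = 0.0572), ELF3 (AT2G25930, 0.13, adjusted p = 0.334) and GI (AT1G22770, 0.12, adjusted p = 0.44), of the evening, and the phases were set beside the genes after their values were seen. The TOC1 call was lost without Col-0 replicate 1 or 2 or any 1 lhp1-6 replicate (adjusted p up to 0.136), and the ELF4 call without Col-0 replicate 1 or 2 or lhp1-6 replicate 1 or 2 (adjusted p up to 0.131). Both were lost with the 6 fruit libraries alone (adjusted p = 0.168 and 0.163) and with array weights (adjusted p = 0.0754 and 0.103). The clock list gave adjusted p = 0.974, with median 0.12 and mean -0.13, and its test direction flipped after median-of-ratios rescaling and quantile normalisation. Of 17 cold response genes 2 rose and 4 fell (adjusted p = 0.0501, and 0.0253, lower, after median-of-ratios rescaling; adjusted p = 0.678 with an estimated correlation, before rescaling). COR27 (AT5G42900, 1.40, adjusted p = 0.000212) and COR28 (AT4G33980, 1.21, adjusted p = 0.000108), which also take part in the clock, rose, and GOLS3 (AT1G09350, -2.34, adjusted p = 0.000898) and COR15B (AT2G42530, -1.34, adjusted p = 0.00486) fell. Of 10 jasmonate genes 2 rose and 1 fell, the rises being the vegetative storage protein genes VSP1 (AT5G24780, 2.79, adjusted p = 2.78e-05) and VSP2 (AT5G24770, 2.96, adjusted p = 0.00948), whose sequences are close. The COR15B and VSP2 calls were lost with the 6 fruit libraries alone (adjusted p = 0.0510 and 0.0927). That list gave adjusted p = 0.974, with median -0.42 and mean 0.15, and its test direction flipped under each of the other scalings.

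The remaining lists gave no call in fruit. None of the 3 pollen markers passed over all genes (limma, 3 at an unadjusted p under 0.05), and 3 were lower adjusted over the list alone (median -0.83, list adjusted p = 0.0917). The nuclear photosynthesis list had 1 rise and 3 falls among 26 genes (adjusted p = 0.633), and the plastid-encoded list had none among 86 (limma, 2 at an unadjusted p under 0.05; 0.392). The seed coat list had 1 rise, of NAC056 (AT3G15510, 1.01, adjusted p = 0.000527), and 2 falls among 15 (list adjusted p = 0.974). Single changes stood in the lists of endosperm (0.633), gibberellin biosynthesis (0.716), flavonoid (0.716), heat shock (0.716), vascular (0.392) and mitochondrion-encoded genes (0.856), each value in brackets being the list's adjusted p. None stood in the lists of auxin (limma, 1 at an unadjusted p under 0.05; list adjusted p = 0.974) and the cell cycle (limma, 0 at an unadjusted p under 0.05; 0.856). The vascular list had a median of -0.06 and a mean of 0.21. The number of changed genes was 875 with the 6 fruit libraries fitted alone, 5730 without Col-0 replicate 1, and 1829 and 1900 without lhp1-6 replicates 2 and 3. Without Col-0 replicate 1 the estimated seed shares did not overlap between genotypes, at 3.69% and 5.65% in Col-0 against 8.31% to 11.2% in lhp1-6. Between 5 lists (without Col-0 replicate 2) and 14 lists (without Col-0 replicate 1) were called against 8 with each library in.

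Seeds of lhp1-6 held more storage protein and late embryogenesis transcripts than Col-0 seeds taken at the same labelled stage. CRU3 stood at 6.89, 48.9 and 2.69 TPM in the Col-0 seed replicates and at 5651, 1555 and 7870 TPM in lhp1-6 seed (8.50, adjusted p = 0.000884). DOG1 stood at 1.17, 1.41 and 0.983 TPM in Col-0 and at 11.9, 4.31 and 15.3 TPM in lhp1-6 (2.25, adjusted p = 0.00318). Of 19946 genes 2410 changed, 369 higher and 2041 lower (15.3% higher). The median over all genes was -0.15, and median-of-ratios rescaling moved it by 0.15. A seed change relative to the other genes thus lies about 0.15 above the value given, and by less for genes near the floor. After that rescaling 988 genes changed, 472 higher and 516 lower (47.8% higher). After quantile normalisation 512 were higher and 557 lower, and with storage and organelle genes taken out of the TPM total 393 were higher and 780 lower. The storage list held 1.81%, 1.87% and 1.15% of the listed TPM in the Col-0 seed replicates and 10.3%, 4.53% and 11.8% in lhp1-6. Changes of at least 1 log2 unit numbered 156 higher and 254 lower.

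**Figure D3:**
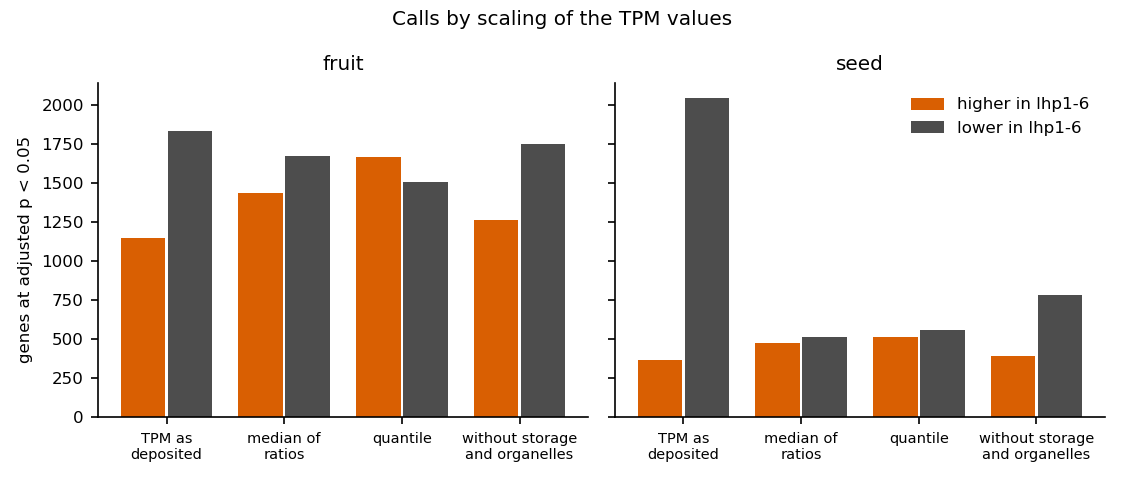
Numbers of genes called higher and lower in lhp1-6 than in Col-0, in fruit and in seed, under 4 scalings of the TPM values. In seed, 369 genes were higher and 2041 lower with TPM as deposited, against 472 and 516 after median-of-ratios rescaling.

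Of the 13 storage genes 6 rose in seed, 9 adjusted over the list alone (median 2.92, 3.10 after median-of-ratios rescaling, adjusted p = 1.77e-17, and 0.167 as adjusted p with an estimated correlation). SESA1 rose from 29.6 ± 5.97 to 2389 ± 1240.0 TPM (6.13, adjusted p = 0.00149), SESA5 by 5.06, CRU1 by 4.74 and CRU2 by 4.71. The CRU2 call was lost without Col-0 replicate 3 or lhp1-6 replicate 1 or 3 (adjusted p up to 0.0684). Of 7 late embryogenesis genes 4 rose (3 after rescaling), 5 adjusted over the list alone (adjusted p = 2.53e-09, and 0.122 as adjusted p with an estimated correlation). LEA76 (AT3G15670, 1.75, adjusted p = 0.0108) and RAB18 (AT5G66400), a dehydrin (2.91, adjusted p = 0.0147), were among them. The first call was lost without Col-0 replicate 3 (adjusted p = 0.0534) and the second without Col-0 replicate 1 (adjusted p = 0.0505). Other large rises were those of LEA (AT2G21490, 4.78), AT1G04560 (4.78), the peroxidase gene AT2G38380 (5.77), and AT5G50600 (4.84) with its copy AT5G50700 (4.84).

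Of 13 dormancy regulators DOG1 and PIL5 (AT2G20180), a light-labile repressor of germination (0.66, adjusted p = 0.038), rose (list adjusted p = 0.00379, 0.0504 after quantile normalisation, and 0.122 as adjusted p with an estimated correlation). MFT, at 469 ± 101 and 668 ± 94.9 TPM, did not pass (adjusted p = 0.577). Of 11 abscisic acid transporters 4 rose and 1 fell, 4 and 2 adjusted over the list alone. The list test pointed higher against a median of -0.06 (adjusted p = 0.00652, 0.175 after rescaling, and 0.167 as adjusted p with an estimated correlation). ABCG20 (AT3G53510, 2.78, adjusted p = 0.00121), ABCG31 (AT2G29940, 0.85, adjusted p = 0.00606), NPF5.1 (AT2G40460, 1.54, adjusted p = 0.0162) and NPF4.6 (AT1G69850), a nitrate transporter that also imports abscisic acid (0.49, adjusted p = 0.0281), rose, and ABCG22 (AT5G06530) fell (-0.84, adjusted p = 0.00189). Of 8 biosynthesis genes ABA2 (AT1G52340) rose (0.29, adjusted p = 0.0468; list adjusted p = 0.29), and of 8 catabolism and conjugation genes BGLU18 (1.11, adjusted p = 0.0276; list adjusted p = 0.169). The calls of PIL5, NPF4.6, ABA2 and BGLU18 were lost without any 1 Col-0 replicate or lhp1-6 replicate 1 or 3 (adjusted p up to 0.157, 0.109, 0.173 and 0.112), and that of ABA2 also with no mean trend (0.0613). That of NPF5.1 was lost without Col-0 replicate 3 or lhp1-6 replicate 1 or 3 (up to 0.0748). Of 21 signalling genes RAB18 rose and RD22 (AT5G25610) fell (-1.04, adjusted p = 0.00244), with list adjusted p = 0.0512. NCED3, at 1.43 ± 0.301 and 0.662 ± 0.373 TPM, did not pass in seed (adjusted p = 0.455).

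Among the largest falls in seed were those of AT1G21475 (-2.93, adjusted p = 0.00106), AT4G18310 (-2.86, adjusted p = 0.0109), AT4G29630 (-2.67, adjusted p = 0.00223), AT1G61090 (-2.58, adjusted p = 0.0038) and AT1G61095 (-2.50, adjusted p = 0.0083). The AT4G18310 call was lost without Col-0 replicate 3 (adjusted p = 0.0504) and with a pseudocount of 0.1 (0.110). AGO3 (AT1G31290), an Argonaute, fell from 30.3 ± 7.11 to 4.47 ± 0.305 TPM (-2.49, adjusted p = 0.00372). AT4G18320 (-2.34), AGP23 (AT3G57690), an arabinogalactan protein (-2.54), and SK8 (AT3G21830), of the Skp1-like family (-2.25), fell too. SK8 is 1 of several close copies, and its call was lost without Col-0 replicate 2 or 3 or lhp1-6 replicate 1 (adjusted p up to 0.0706). All 3 pollen markers fell (2 after rescaling), with list adjusted p = 0.00735 (0.386 as adjusted p with an estimated correlation). VGD1 (AT2G47040) fell from 12.3 ± 8.11 to 1.80 ± 0.666 TPM (-2.11, adjusted p = 0.00564), and AGP11 (AT3G01700, -1.44, adjusted p = 0.00776) and AGP6 (AT5G14380, -1.24, adjusted p = 0.0242) fell as well. The AGP6 call was lost after rescaling and quantile normalisation (adjusted p = 0.0585 and 0.0724) and without Col-0 replicate 1 or 3 or lhp1-6 replicate 1 or 3 (adjusted p up to 0.0998).

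Of 15 seed coat and mucilage genes 10 fell, 12 adjusted over the list alone, and 1 fell after median-of-ratios rescaling (median -0.51, -0.34 rescaled, adjusted p = 0.000126, and 0.252 as adjusted p with an estimated correlation). PER36 (AT3G50990), a peroxidase that loosens the mucilage cell wall, changed by -2.06 (SE 0.39, adjusted p = 0.00966). Of 15 MADS-box genes 2 rose and 6 fell (adjusted p = 0.573). SEP4 (0.92, adjusted p = 0.00547) and PI (0.93, adjusted p = 0.0057) rose, while SEP3 (-0.81, adjusted p = 0.00252) and AG (AT4G18960), the organ identity gene AGAMOUS (-1.35, adjusted p = 0.000477), fell. Of 16 flowering time genes 3 rose and 2 fell (list adjusted p = 0.128), among them SOC1 (AT2G45660, 1.02, adjusted p = 0.00228) and AGL19 (0.70, adjusted p = 0.0107), both higher. The AGL19 call was lost without lhp1-6 replicate 1 or 3 (adjusted p up to 0.0539). With a pseudocount of 5 the calls of SEP4 (0.28, adjusted p = 0.189) and AGL19 (0.18, adjusted p = 0.108) were lost, both being near the floor in Col-0 seed, at 0.226 ± 0.00119 and 0.104 ± 0.0260 TPM. FLC (-0.41, adjusted p = 0.433) and FT (-0.47, adjusted p = 0.249) did not pass. Both passed with array weights (0.0241 and 0.0144), and FLC with the 6 seed libraries alone (0.0196).

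Photosynthesis and several other-tissue lists were called higher in seed with few single genes. Of 26 nuclear photosynthesis genes 2 rose (median 0.11, adjusted p = 2.71e-07, 0.218 after quantile normalisation, and 0.575 as adjusted p with an estimated correlation), namely RBCS1B (AT5G38430, 0.60, adjusted p = 0.0319) and RBCS3B (AT5G38410, 0.71, adjusted p = 0.036), close copies whose reads may be split. The RBCS1B call was lost without Col-0 replicate 1 or 2 or lhp1-6 replicate 1 or 3 (adjusted p up to 0.125) and with a pseudocount of 5 (0.0859), and the RBCS3B call without any 1 library (up to 0.131). None of 86 plastid-encoded genes changed (limma, 1 at an unadjusted p under 0.05), and the list test pointed higher against a median of -0.10, which turned to 0.05 after rescaling (adjusted p = 0.00381, 0.747 after rescaling, and 0.812 as adjusted p with an estimated correlation). These genes summed to 509, 1478 and 455 TPM in lhp1-6 seed replicates 1, 2 and 3, so replicate 2 stood apart, and to 848, 834 and 623 TPM in Col-0. TGG1 rose (2.56, adjusted p = 0.0184) as 1 of 10 glucosinolate genes (adjusted p = 0.000192, 0.0678 rescaled, and 0.167 as adjusted p with an estimated correlation). MYB60 (AT1G08810), a guard cell factor, rose from 6.29 ± 3.43 to 32.4 ± 4.29 TPM (2.28, adjusted p = 0.0032) as 1 of 6 guard cell markers (list adjusted p = 0.00379, 0.122 rescaled, and 0.158 as adjusted p with an estimated correlation). SUC2 (AT1G22710), the phloem sucrose transporter, rose (0.77, adjusted p = 0.0189) as 1 of 5 vascular markers (list adjusted p = 0.00793, 0.216 rescaled, and 0.348 as adjusted p with an estimated correlation). The TGG1 and SUC2 calls were lost without Col-0 replicate 3 or lhp1-6 replicate 1 or 3 (adjusted p up to 0.0838 and 0.0860), the latter also without Col-0 replicate 2.

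Of 11 clock genes 3 fell, calls that were lost after rescaling (list adjusted p = 0.804; the median turned from -0.09 to 0.04). They included CCA1 (-0.72, adjusted p = 0.0184) and LHY (-0.93, adjusted p = 0.0236). These were also lost without Col-0 replicate 1 or 2, without lhp1-6 replicate 3, and for CCA1 also without lhp1-6 replicate 1 (adjusted p up to 0.0812 and 0.104), and after quantile normalisation (0.0870 and 0.0848), LHY also without storage and organelle genes (0.0505). After rescaling the flavonoid list (0.00398, against 0.169 before) and the mitochondrion-encoded list (5.94e-05, against 0.0887) were called lower as well. With an estimated correlation, before rescaling, these gave adjusted p = 0.812 and 0.838. Of the other lists, 4 Polycomb genes of 25 and 2 cold genes of 17 fell, 1 valve margin gene of 13 rose and 4 fell, and 1 secondary wall gene of 21 rose and 3 fell, all without a list call (adjusted p = 0.19, 0.956, 0.453 and 0.825). No member of the salicylic acid, cell cycle, embryo, endosperm, jasmonate or senescence lists changed in seed (limma, with 0, 0, 1, 1, 1 and 3 at an unadjusted p under 0.05). In seed 727 genes changed without Col-0 replicate 3, 990 without 2, 1330 without 1, 676 without lhp1-6 replicate 1 and 662 without 3. Fitting the 6 seed libraries alone gave 5356.

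The genotype effect was tested for a difference between the tissues, which asks where the change was not of the same size. A gene hardly expressed in seed can also pass, by its change in fruit alone. It differed for 1100 genes, 343 with a higher and 757 with a lower effect in seed (31.2% higher), and for 497 (169 and 328) with the replicate number as a block. The median over all genes was -0.14, which median-of-ratios rescaling moved by 0.13, and rescaled values gave 373 and 374 (49.9% higher). Numbers without single libraries were 4085 (Col-0 fruit replicate 1), 683, 474 and 437 (Col-0 seed replicates 1, 2 and 3), and 458 and 427 (lhp1-6 seed replicates 1 and 3).

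AT5G39150, NAP and NCED3 fell in fruit and changed by 0.17, 0.12 and -0.56 in seed. The difference was 3.10 (SE 0.32, adjusted p = 0.000712) for AT5G39150, 3.16 (SE 0.59, adjusted p = 0.0142) for NAP and 3.14 (SE 0.67, adjusted p = 0.0248) for NCED3. ELP (AT1G12090, 3.43, adjusted p = 0.00266) and AT5G66780 (3.73, adjusted p = 0.00917) had the largest positive differences beside these, with lower values in lhp1-6 fruit (-2.37 and -1.95). In seed these 2 genes changed with the opposite sign (1.06 and 1.785). The largest negative differences were those of TGG2 (-3.72, adjusted p = 0.0288), AT2G05540 (-3.46, adjusted p = 0.00155), AT4G05475 (-3.37, adjusted p = 3.56e-05), MYB29 (-3.305, adjusted p = 0.00206) and AT5G54360 (-3.26, adjusted p = 3.56e-05), each raised in lhp1-6 fruit. Their seed changes were 0.04, 0.39, 0.39, 0 and 0.12 in the same order. Some of these genes were low in seed, which leaves little room for a fall there. The mean in lhp1-6 seed was 0.0865 TPM for AT5G54360 and 1.04 TPM for AT4G05475. NCED3 was low in seed of both genotypes, as given above. For the other genes, whether a change near 0 in seed came from low expression there was not sorted out. With the block the adjusted p of NCED3 was 0.0591, that of TGG2 0.0537 and that of LHP1 0.0531, against 0.0124 for LHP1 without it. With a pseudocount of 0.1 the calls of NCED3 and TGG2 were lost (adjusted p = 0.0607 and 0.0502), and with the block and rescaling together that of AT5G66780 (0.0555). NCED3 lost its call without Col-0 fruit replicate 3, lhp1-6 fruit replicate 1, Col-0 seed replicate 2 or 3, or lhp1-6 seed replicate 1 or 3 (adjusted p up to 0.0681). TGG2 lost it without Col-0 fruit replicate 2, lhp1-6 fruit replicate 2 or 3, any 1 Col-0 seed replicate, or lhp1-6 seed replicate 1 or 3 (up to 0.0743).

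Lists whose effect was higher in seed than in fruit were abscisic acid signalling (1 of 21 genes, 4 higher and 1 lower adjusted over the list alone, adjusted p = 2.03e-07), salicylic acid defence (1 of 9, 5 adjusted over the list alone, 2.17e-05), abscisic acid catabolism (1 of 8, 3 adjusted over the list alone, 0.00193) and senescence (2 of 15, 4 adjusted over the list alone, 0.00202). With an estimated correlation these gave adjusted p = 0.519, 0.0645, 0.475 and 0.571. Nuclear photosynthesis genes (0 of 26, limma, 4 at an unadjusted p under 0.05; 2.21e-05) were called higher too (adjusted p = 0.703 with an estimated correlation). Plastid-encoded (0.00202), secondary wall (0.0186) and late embryogenesis genes (0.0264) were called higher but not after median-of-ratios rescaling (each 0.148), nor with an estimated correlation (adjusted p = 0.879, 0.763 and 0.571). That rescaling also added lists called lower in seed, with 5 lists higher and 4 lower, against 8 and 1 before. The seed coat list was lower in seed (2 of 15, 4 adjusted over the list alone, 0.00758, and adjusted p = 0.571 with an estimated correlation). None of the 13 storage genes differed in effect between the tissues (limma, 0 at an unadjusted p under 0.05, list adjusted p = 0.827). SEP3 and SEP4 had effects of opposite sign in fruit and seed, with differences of -1.58 (SE 0.16, adjusted p = 0.000634) and 2.01 (SE 0.21, adjusted p = 0.000758).

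Genes changed in both tissues were counted by direction. There were 121 higher in both, against 21.2 for independent lists, and 424 lower in both, against 187.7. The lists were not independent, since same-numbered fruit and seed libraries deviated together and each fruit library held transcripts of seed genes, so no p is given. With the seed share taken off the fruit libraries, chosen after seeing the data, 88 were higher in both, against 42.5 for independent lists, and 464 lower, against 252.6. Genes higher in fruit and lower in seed numbered 54, and the reverse 13. LHP1, TGG1, AGL19 and PI were among those changed the same way. So were CRU3 and SESA1, which lost their fruit call with the seed share taken off (adjusted p = 0.0534 and 0.172), and CCA1 and LHY, which lost their seed call after median-of-ratios rescaling (adjusted p = 0.0543 and 0.0665). The seed calls of TGG1 and AGL19 were lost without single libraries, as given above. Across the 19946 genes, which are not independent replicates, the changes in the tissues correlated with Pearson's r 0.435 and Spearman's rho 0.336. The number changed in both the same way was 545, and 305 after median-of-ratios rescaling (149 higher and 156 lower). After quantile normalisation 167 were higher and 138 lower, and without storage and organelle genes 123 and 214. The excess of shared falls thus depended on the scaling. Without single libraries the number was 332, 319 and 251 (Col-0 seed replicates 1, 2 and 3), 224 and 216 (lhp1-6 seed replicates 1 and 3), and 312 and 334 (lhp1-6 fruit replicates 2 and 3).

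Seed and fruit differed in most genes, which also checks the tissue labels. In Col-0 16558 of 19946 genes differed, 9033 higher in seed and 7525 lower, and in lhp1-6 16038 (7834 and 8204). Median-of-ratios rescaling moved the Col-0 median of 0.12 by -0.15, with 8034 higher and 8530 lower. Quantile normalisation gave 9146 higher and 6958 lower in lhp1-6. The genes with the largest excess in Col-0 seed were SESA2 (4.21), AT2G27380 (4.19), SESA4 (AT4G27170, 4.16), SESA3 (AT4G27160, 4.04) and CRU2 (3.87). The Col-0 fruit libraries held an estimated seed RNA share of 3.69% to 23.4%, and both the sizes and the order changed with it taken off, an alternative chosen after seeing the data. The values were then 7.31 for SESA2, 8.96 for AT2G27380, 7.94 for SESA4, 7.69 for SESA3 and 5.32 for CRU2. Fruit held more of AT1G23130 (-9.76), CTL2 (AT3G16920), a chitinase-like gene (-9.34), GLN1;4 (AT5G16570), a glutamine synthetase (-9.20), AT1G22480 (-9.09) and AT2G47880 (-8.83). FT stood at 2087 ± 522 TPM in Col-0 fruit and 13.7 ± 3.40 TPM in Col-0 seed.

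The values after the medians, and those standing alone in brackets, are list adjusted p. In Col-0, all 13 storage genes (median 3.70, 0.0125), all 7 embryo regulators (2.99, 0.0196) and all 15 cell cycle genes (2.60, 0.000745) were higher in seed. Polycomb genes were higher in 22 of 25 and lower in 2 (0.000745), and flavonoid genes higher in 16 and lower in 4 of 22 (0.0457, a call lost after quantile normalisation, 0.0642, and without storage and organelle genes, 0.054). Lower in seed were 20 of 21 secondary wall genes with 1 higher (median -3.31, 5.04e-08), all 15 senescence genes (6.85e-05), 24 of 26 photosynthesis genes (1.85e-05), all 10 glucosinolate genes (0.000745), all 9 salicylic acid genes (0.00455), all 5 vascular markers (0.00365), 19 of 21 abscisic acid signalling genes (9.8e-05), 12 of 17 cold genes (0.00166) and 10 of 11 clock genes (0.00172). MADS-box genes were lower in 10 and higher in 4 of 15 (0.0217), and flowering time genes lower in 11 and higher in 4 of 16 (0.039, 0.0504 with the replicate block and 0.0611 after median-of-ratios rescaling). Seed oil genes were higher in 8 and lower in 1 of 9 (adjusted p = 0.0554, 0.0369 with the block and 0.0334 after median-of-ratios rescaling), and all 3 pollen markers were lower (0.0554, 0.0457 after quantile normalisation). Over these lists the counts adjusted over the list alone were the same.

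In lhp1-6 16 lists were called as well. They left out salicylic acid defence (adjusted p = 0.0958) and flavonoids (0.0524, 0.0378 with the block) and added seed oil (0.0344) and plastid-encoded genes (0.0444), and the flowering time call (0.0487) was lost with the block (0.0623) and after median-of-ratios rescaling (0.0507). After quantile normalisation the calls of seed oil (0.104), plastid-encoded (0.104) and storage genes (0.0502) were lost and that of pollen markers gained (0.0354, against 0.0524). Without storage and organelle genes seed oil was lost (0.0522) and pollen gained (0.045). With an estimated correlation no list was called between the tissues, the smallest adjusted p being 0.331 in Col-0 and 0.460 in lhp1-6 (3 and 2 lists at an unadjusted p under 0.05).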

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

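The tests of seed RNA in fruit, of dilution by it, of Col-0 fruit replicate 1, of the time of day and of the TPM share were chosen only after the results were seen, and the splits of the samples were planned.

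The genotype effect of lhp1-6 differed between seed and fruit, by limma's test of the difference itself, for 1100 genes, 497 with the replicate block. Of the genes named in the text 50 were among them, 35 also with the block. The values given are the seed effect minus the fruit effect on the log2 scale. The seed change itself was 0 for MYB29 and AT4G10290 and -1e-04 for CYP707A2. There the difference is the fruit change with its sign turned.

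Among genes lower in lhp1-6 fruit the difference was 3.08 for AT3G59845, 3.16 for NAP, 3.10 for AT5G39150, 3.04 for AT5G39180, 2.88 for AT5G59330, 2.72 for WSD1 and 2.65 for AT4G10290. It was 1.34 for CYP707A2, 1.41 for GA2OX1, 2.15 for TSF, 2.29 for GOLS3, 2.01 for SEP4, 3.43 for ELP and 3.73 for AT5G66780. It no longer passed with the block for NCED3 (3.14), ABA1 (0.52), AFP1 (2.13), PAD4 (0.80), NAC092 (0.90) and STM (1.41).

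Among genes higher in lhp1-6 fruit it was -3.30 for MYB29, -2.19 for AGL19, -1.58 for SEP3, -0.72 for LUX, -1.17 for COR27, -0.92 for COR28, -2.77 for VSP1, -1.75 for ADPG1, -0.97 for SHP1, -1.52 for NAC056 and -1.36 for VIN3. It was -2.50 for GATA13, -2.32 for CDG1, -2.43 for AT3G47030, -3.37 for AT4G05475, -2.46 for AT4G05470, -3.26 for AT5G54360 and -3.46 for AT2G05540, genes named for their values in lhp1-6 fruit after these were seen, apart from AT4G05475, AT5G54360 and AT2G05540. For DTX50 (-1.23), TGG2 (-3.72) and XCP1 (-1.02) it no longer passed with the block.

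Among genes changed in seed it was 2.33 for LSH10, also chosen after its values were seen, -0.79 for ABCG22 and 1.32 for SOC1. It no longer passed with the block for LHP1 (-0.76), AT1G21475 (-2.28), AT4G29630 (-2.30), PIL5 (1.11), ABCG31 (0.84) and AG (-0.79).

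For the difference between tissues, 3 of 100 drawn splits of the libraries gave at least as many genes as the real 1100. The highest other split called 4522 genes and was the one with the genotypes of all seed libraries swapped, which turns the difference of the effects into their sum. The next called 2100 and grouped Col-0 fruit replicate 1 (estimated seed share 23.4%) with lhp1-6 fruit replicates 2 (11.2%) and 3 (9.12%), against 3.69% to 8.31% in the other fruit libraries. The first points to a structure of the samples, namely the genotypes themselves, and what makes the second call so many genes was not tested. Compared with the 7 drawn splits that part no fruit and seed pair, the real one included, the highest other gave 0, and those others mix genotypes within a tissue. The other comparisons have 10 splits each, too few for a share under 0.05, and 1 split, the real one, reached its count in each. The real count and the highest other were 2980 and 296 in fruit, 2410 and 0 in seed, 16558 and 0 for the tissues in Col-0, and 16038 and 0 in lhp1-6 (limma, adjusted p).

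Storage protein genes were higher in lhp1-6 fruit, with a list median of 3.94. A larger share of seed RNA in lhp1-6 fruit is argued against as the sole explanation. The largest lhp1-6 share over the smallest Col-0 share is 1.6 on the log2 scale, below that median. The mean shares were 9.54% in lhp1-6 and 10.9% in Col-0, but the Col-0 mean rests on replicate 1 (23.4%). Each lhp1-6 share (8.31%, 11.2% and 9.12%) lay above those of Col-0 replicates 2 and 3 (3.69% and 5.65%). A candidate explanation is seed RNA in both fruit groups combined with the rise of storage transcripts in lhp1-6 seed, since the fruit over seed ratio of the called members divided by the estimated share had a median of 0.12 (log2), from -0.473 to 0.771 per library. With the share taken off, 0 of the 9 called members passed (limma) while their median change went from 5.47 to 3.12 and their median SE from 0.846 to 1.906, so the calls ended because the change shrank and the spread grew. Both steps used the genotype's mean seed TPM rather than the same-numbered seed library, and subtracted values below 0 were set to 0. Part of the larger spread may come from that, so the lost calls do not show that no rise was left. A rise within the fruit tissue of lhp1-6 stays open and was not tested.

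The 18 abscisic acid biosynthesis, abscisic acid signalling, salicylic acid and senescence genes called lower in lhp1-6 fruit had a median change of -0.87. Dilution by seed RNA is argued against, as it could lower them by -0.17 at most and with the share taken off the median was -0.92, with 18 called. The falls did not rest on Col-0 fruit replicate 1, since without it the median of the 18 was -1.003. All 18 were called without it (17 without replicate 2 and 15 without replicate 3). That count says little, as the 18 were chosen with the library in and calls over all genes rose from 2980 to 5730 without it. Another time of day at dissection remains a candidate explanation, since evening minus morning clock genes differed by 1.698 in fruit (0.585 in seed), 3 of 4 morning genes being lower and 3 of 6 evening genes higher (2 and 0 in seed), in classes chosen after the values were seen. The dissection times are not given in the sources used here, and an effect of LHP1 itself on these genes and on the clock stays open and was not tested.

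In seed, more genes were lower than higher, and storage genes were higher. With storage and organelle genes taken out of the TPM total 33.5% of calls were higher (393 higher and 780 lower), against 15.3% before, and the median over all genes went from -0.15 to -0.05. Whether a larger part of the total taken by such genes accounts for the whole excess of falls stays open, as the excess shrank and did not end. For the storage genes, faster maturation of lhp1-6 seed, or loss of repression at these genes, stays open, and neither was tested.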

How the results depend on the processing

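Alternatives that take off the seed share, and the block with rescaling, were chosen after seeing the data, and the others were planned. LHP1 kept its direction and call throughout, from -4.26 to -1.92 in fruit and from -5.60 to -2.33 in seed. Where a count moved by over 1.5 times the cause was not tested, except that a minimum of 1 log2 unit keeps fewer genes by construction. The main fit shares the spread of each gene over all 12 libraries, so the fruit p-values draw on the seed libraries and the reverse. With the 6 libraries alone it comes from those only. Replicates correlated at 0.9532 to 0.9859 in Col-0 fruit and 0.9839 to 0.988 in lhp1-6 fruit (Pearson's r). In seed the values were 0.9921 to 0.9945 in Col-0 and 0.9893 to 0.9947 in lhp1-6.

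In fruit the 2980 changed genes became 875 with the 6 libraries alone, 732 with a minimum of 1 log2 unit, 4768 with the seed share taken off, and 1829 to 5730 with single libraries left out. In seed the 2410 became 988 after median-of-ratios rescaling, 1069 after quantile normalisation, 1173 without storage and organelle genes, 5356 with the 6 libraries alone, 10033 with array weights, 410 with a minimum of 1 log2 unit, and 662 to 2511 with single libraries left out. The 1100 genes that differed in effect became 4214 with array weights, 492 with a minimum of 1 log2 unit, 3057 with the seed share taken off, and 427 to 4085 with single libraries left out. The tissue counts became 8991 in Col-0 and 8234 in lhp1-6 with a minimum of 1 log2 unit. The 545 genes changed in both tissues became 305 after rescaling and 305 after quantile normalisation, 337 without storage and organelle genes, 287 with the 6 libraries alone, 1282 with array weights, 80 with a minimum of 1 log2 unit, and 216 to 644 with single libraries left out. With an estimated correlation the list tests called 0 lists in each comparison (camera), and with the seed share taken off 5 in fruit against 8. Left-out libraries gave 5 to 14 lists in fruit.

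The replicate numbers pair fruit and seed within a genotype, and with the replicate block 497 genes differed in effect, 346 with rescaling as well. Across genotypes the numbers do not pair the samples (correlations -0.246, -0.397 and 0.06 in fruit, 0.421, -0.029 and 0.125 in seed), not every sample correlated best with its own number, and the block there gave 1664 genes in fruit, 788 in seed and 183 in both, with 10 lists called in fruit and 15 in seed. Between the tissues the block moved the list calls of flowering time and seed oil in Col-0 and of flowering time and flavonoids in lhp1-6, and it changed no call among the lists of the difference.

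Of the named genes called in fruit, 42 of 76 kept their call under each alternative, 17 lost it only with the 6 libraries alone and 9 only with the seed share taken off. In seed 31 of 50 kept it, in the difference 7 of 10, and between the tissues in Col-0 10 of 10. The one reversed value was that of FT in fruit, uncalled, at 0.095 without Col-0 fruit replicate 3, in a range from -0.27 over left-out libraries. TPM without counts leaves the depth of low genes unknown.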

Other observations

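The tests of neighbouring genes were planned before their result was seen, and the genes in the next paragraph were chosen for it after their values were seen. Of these, AT5G54360 and AT4G05475 had also been named by the planned rule for the difference between tissues.

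Some genes were near 0 in Col-0 fruit and expressed in each lhp1-6 fruit library. GATA13 (AT2G28340), a GATA transcription factor, went from 0.0203 ± 0.0352 to 7.10 ± 0.821 TPM (2.98, adjusted p = 3.64e-07), and CDG1 (AT3G26940), a kinase of brassinosteroid signalling, from 0.428 ± 0.245 to 6.25 ± 0.710 TPM (2.35, adjusted p = 5.7e-06). AT3G47030 (0.598 ± 0.138 to 8.59 ± 0.467 TPM), AT5G54360 (0.104 ± 0.0396 to 10.6 ± 2.07 TPM) and AT4G05475 (0.236 ± 0.0994 to 15.7 ± 1.32 TPM) did likewise. In seed, LSH10 (AT2G42610), of the family of LIGHT SENSITIVE HYPOCOTYLS genes, went from 0.0451 ± 0.0451 to 16.0 ± 2.46 TPM (4.02, adjusted p = 1.6e-07), and it also rose in fruit (1.69, adjusted p = 5.09e-05).

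Changed genes lay next to each other more often than under random placement. The order was taken among 19808 tested genes, so genes not tested can lie between the members of a pair. Among 731 genes changed by at least 1 log2 unit in fruit, 47 adjacent pairs changed in the same direction (21 higher, 26 lower), against a mean of 13.9 and a highest value of 30 in 10000 permutations (permutation p = 1e-04, the smallest they can give). Among 410 in seed there were 26 such pairs (4 higher, 22 lower), against a mean of 4.44 and a highest value of 14 (permutation p = 1e-04, the smallest they can give). Examples, chosen after the values were seen, are AT4G05470, listed at 0 in Col-0 fruit and at 4.93 ± 0.9996 TPM in lhp1-6 fruit, beside AT4G05475, and AT2G05540 (3.85) beside GRP-3 (AT2G05520, 3.05), whose call was lost with the 6 fruit libraries alone (adjusted p = 0.0903). In seed AT1G61090 (-2.58) and AT1G61095 (-2.50) lie on either side of AT1G61093 (-1.79), which fell as well. The higher pairs in fruit include CRU2 with AT1G03890 and the run of SESA1, SESA2, SESA3 and SESA4. For storage genes in fruit, seed RNA is a candidate explanation, as given above. The pairs were not sorted into tandem copies and other neighbours, so what they share was not tested.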
